A study of Mus musculus with 12 samples.

How the data were processed

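RNA was sequenced from microglia sorted out of the spinal cord of Biozzi ABH mice with chronic-relapsing experimental autoimmune encephalomyelitis (EAE) and of control mice. The 12 libraries fell into 4 groups of 3 by their titles: control, acute phase, remission and chronic phase. Per the labels' protocols, cells positive for CD11b, intermediate for CD45 and negative for Ly-6C were sorted, RNA was reverse transcribed with random primers, and libraries were made with a transposase kit that does not keep the strand. All libraries were run together as single reads, per the labels' protocols. The replicate number used here is the order of the records within a group and pairs no mice.

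Per the submitters' processing notes, reads were aligned with HISAT2 to the mouse genome GRCm38, handled with SAMtools 1.3.1 and Picard 2.6.4, and assigned to genes with HTSeq 0.6.1. The notes give no HISAT2 version, no HTSeq settings and no annotation release. The values the authors deposited are counts of reads per gene, given once per library and once as a table of the whole series. The 12 single files equalled their columns of that table in every gene, so the counts of the single files were used. Each file held 48526 Ensembl gene IDs. Of these, 48144 were found in GENCODE release M21, which gave symbols and coordinates on GRCm38, and the 382 others held 0.02078% of all counts. Reads shared by near-identical genes, or by a gene and its antisense partner, cannot be told apart in these counts. Values of the H2, Ly6 and hemoglobin families and of Hspa1a and Hspa1b are therefore uncertain.

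Total counts ranged from 3992885 to 5712376 per library. The 6 features with the most counts (CT010467.1, Lars2, Mir6236, Gm26917, Gm15564 and Gm23935) held 48.3 to 64.1% of a library. Outside these features and the mitochondrially encoded genes, 1266782 to 2496096 counts remained, and this number set the precision. A group with 0 counts of a gene was given a floor of 3 counts over its 3 libraries, and folds against it are written as "at least". The floor stood at 0.173 CPM, the count scaled to its library size, in control, 0.273 in acute, 0.208 in remission and 0.216 in chronic libraries. Where a group held 1 to 3 counts, the ratio is given with its exact 95% counting interval. These folds and ratios use counts pooled over the 3 libraries of a group, so they differ somewhat from ratios of mean CPM. Floors and intervals cover counting error only, because the reads carried no molecular identifiers.

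Genes were kept by the default filter of edgeR 4.0.16 (filterByExpr), which left 12545 for testing in R 4.3.3. A single model of the 4 groups was fitted to all 12 libraries with trimmed-mean-of-M (TMM) factors, and 6 comparisons between groups were tested with edgeR's robust quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested. A gene counts as changed at an adjusted p under 0.05. Levels are CPM after TMM scaling, written as mean ± SD over the 3 mice of a group, and a log2 fold change stands with its standard error (SE). The fit was tested on simulated data drawn from the means of the control libraries, with 50 genes changed at each of 4 folds. In the simulated acute against control comparison, with 11275 genes tested, 10% of genes changed by 1.5-fold were recovered, 40% at 2-fold, 78% at 4-fold and 88% at 8-fold. Of 111 genes called there, 3 had not been changed. Small changes are therefore often missed at this depth.

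Before the data were examined, 32 lists of genes with known roles in microglia, in inflammation or in other cell types were written down, together with the design, the alternatives and the rule for naming genes. A list was tested where at least 3 members passed the filter, and the numbers of members that rose or fell are given over all genes tested and, in places, adjusted over the list alone. Lists were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, and the 186 list tests were adjusted together. Correlations estimated per list, and the rotation test fry, were alternatives. Fry's PValue tests whether the genes of a list move on balance in one direction, its Mixed value whether they change in either direction, and neither compares the list with other genes.

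The genes named follow the fixed rule. For each comparison these are up to 6 genes per direction with the largest change among those with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups, with predicted genes, pseudogenes and mitochondrially encoded genes left out. Up to 4 members with the smallest p of each list described were added, and P2ry12, Tmem119, Cx3cr1, Ptprc, Itgam, Ly6c1 and Ly6c2 were followed in every group as checks of the sort. Genes named outside this rule are marked as chosen after their values were seen.

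The alternatives were DESeq2 size factors in edgeR, library totals alone, DESeq2 1.42.0, limma-voom with quality weights, no filter, a filter of 50 counts in 3 libraries, ribosomal and mitochondrially encoded genes left out, only the 6 libraries compared, the number at the end of each title as a covariate, and each of the 12 libraries left out in turn. The title number is 2 for acute replicates 1 and 2, control replicate 1 and remission replicate 1, and its meaning is not given in the sources used here. A pair of alternatives was added after the data had been seen, namely leaving out remission replicates 1 and 3 together and leaving out the 6 features with the most counts together with all mitochondrially encoded genes. Principal components were taken from log2 CPM of the 2000 most variable genes with a prior count of 2. Sequence reads were not analysed here. No value column of the files was left out.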

Results

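Gene expression was measured by RNA sequencing in microglia sorted from the spinal cord of mice at successive stages of chronic-relapsing EAE, an induced autoimmune disease of the central nervous system used as a model of multiple sclerosis. The 4 groups were control mice, mice in the acute phase, mice in remission and mice in the chronic phase, with 3 mice per group. Total counts ranged from 3992885 to 5712376 per library. The 6 features with the most counts took 53.6 ± 4.55% of the counts in control, 63.2 ± 0.886% in acute, 58.1 ± 2.08% in remission and 59.8 ± 3.13% in chronic libraries (SD, n = 3). Mitochondrially encoded genes took 2.07 ± 0.192%, 5.48 ± 0.285%, 3.26 ± 0.674% and 3.88 ± 0.747% in the same order. After these were set aside, 1266782 to 2496096 counts per library remained, and 17775 to 20265 genes had a count.

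Libraries of a group resembled each other more than they resembled libraries of acute mice. Across genes, which are not independent replicates, Pearson's r of log2 CPM lay between 0.926 and 0.975 within groups and between 0.713 and 0.86 between acute libraries and the others. Between the other groups r lay between 0.891 and 0.96. The first principal component held 65.1% of the variance and set acute libraries, at 75.2 to 88.2, apart from control libraries, at -50.1 to -47.3. The second held 13.4%. Any difference among the 4 groups was called for 5517 genes, which is 44% of the 12545 tested.

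**Figure D1:**
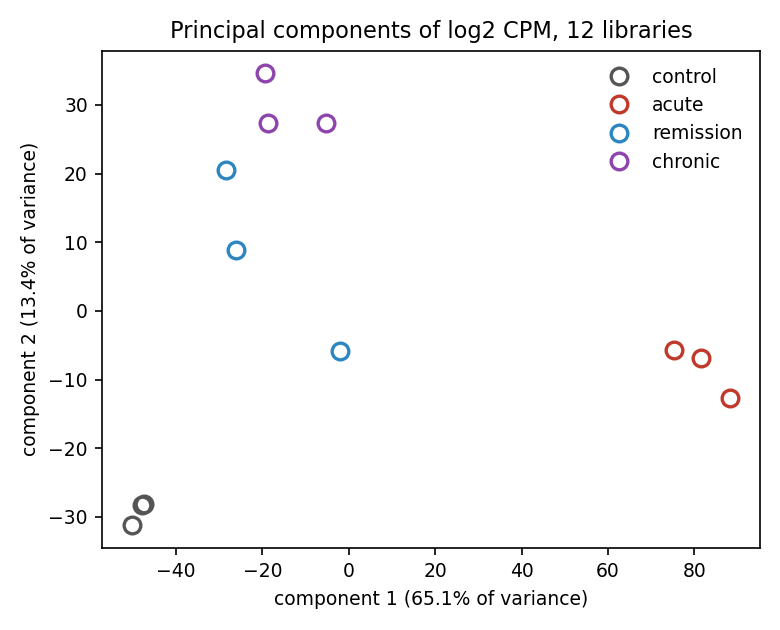
Each open circle is a library placed by its first principal component (horizontal axis, 65.1% of the variance) and its second (vertical axis, 13.4%), in units of log2 CPM scores, coloured by group. Acute libraries lie at 75.2 to 88.2 on the first component, and remission replicate 1, at -2.01, lies nearest to them among the other libraries.

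**Figure D2:**
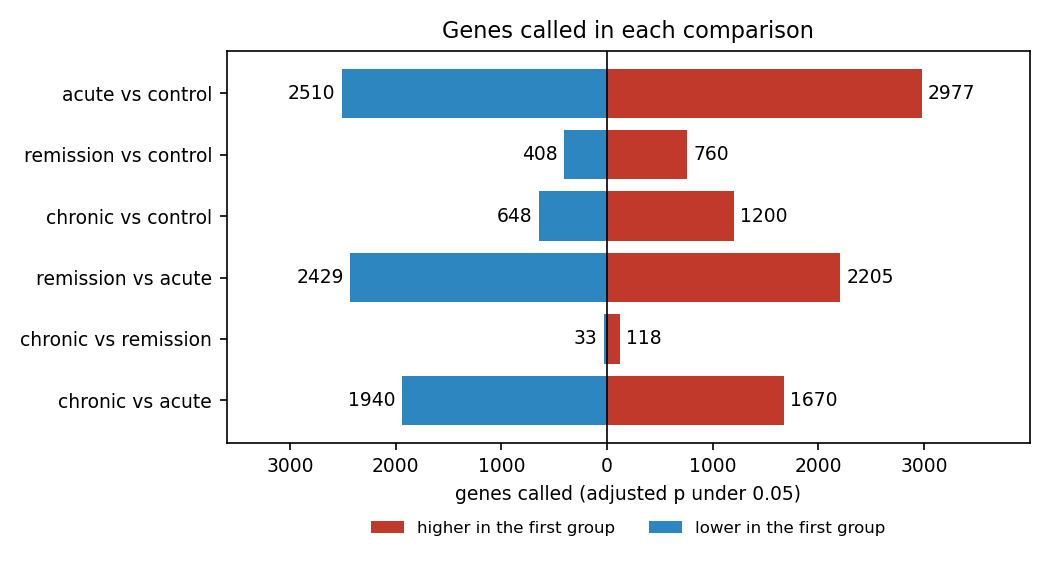
Bars give the number of genes called in each of the 6 comparisons at an adjusted p under 0.05, to the right for genes higher in the first group and to the left for genes lower in it. The bars hold 5487 genes for acute against control and 151 for chronic against remission, and with library totals alone the share of higher genes fell from 54.3 to 22.8% and from 78.1 to 61.4%.

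Genes of the surface proteins used for sorting, and of microglial identity, were followed as checks. Ptprc, which encodes CD45, stood at 422 ± 36.1 CPM in control, 424 ± 23.1 in acute, 427 ± 51.7 in remission and 377 ± 41.2 in chronic mice, and its change passed in none of the 6 comparisons. Itgam, which encodes CD11b, stood at 132 ± 14.7, 86 ± 21.1, 100 ± 18.3 and 175 ± 48.6 CPM. It was lower in acute than in control mice (adjusted p 0.029), a call that ended without control replicate 1, control replicate 3 or acute replicate 1, and higher in chronic than in acute mice (adjusted p 0.00219). Ly6c2, a gene of the Ly-6C antigen that the sort excluded, had 0 counts in control mice and stood at 64.6 ± 19 CPM in acute, 0.389 ± 0.399 in remission and 0.205 ± 0.185 in chronic mice. Its neighbour Ly6c1 reached 0.353 ± 0.408 CPM in acute mice and had 0 counts in the other groups.

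The comparison of acute with control mice asked how the sorted cells changed at the first attack. It called 5487 genes, 2977 higher and 2510 lower, and 2001 of the higher and 1402 of the lower changed by more than 2-fold. All 24 genes typical of resting, or homeostatic, microglia fell, with a median log2 fold change of -2.38, in libraries whose monocyte genes summed to 1870 to 2850 CPM against 24.9 to 68 CPM in control libraries. The counts do not separate a change within microglia from a change in the cells sorted. Fcrls (ENSMUSG00000015852), an Fc receptor-like gene of resident microglia on chromosome 3 from 87250758 to 87263738, fell from 103 ± 10 to 0.365 ± 0.404 CPM (log2 fold change -8.04 ± 0.38 SE, adjusted p 3.81e-11). Olfml3, which encodes a secreted matrix protein, fell from 290 ± 12.2 to 3.8 ± 1.64 CPM, and Gpr34, a lysophospholipid receptor, from 323 ± 14.6 to 21.3 ± 4.84 CPM. The purinergic receptor P2ry12 fell from 679 ± 93 to 66.5 ± 18.8 CPM, the membrane protein Tmem119 from 972 ± 68.2 to 187 ± 47.4 CPM and the fractalkine receptor Cx3cr1 from 2190 ± 118 to 431 ± 141 CPM. Cystatin C, Cst3, fell from 2090 ± 440 to 145 ± 25.9 CPM. Of 24 genes known to be raised in damage-associated microglia, 15 rose and 4 fell (median 2.07). The galectin Lgals3 rose from 0.668 ± 0.737 to 128 ± 19.9 CPM, the tetraspanin Cd63 from 9.48 ± 0.691 to 43.4 ± 7.55 CPM and the phagocytic receptor Axl from 28.4 ± 11 to 372 ± 30.2 CPM.

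Among the largest fitted increases at the acute phase were genes without a count in control mice. Chil3 (ENSMUSG00000040809), a chitinase-like protein gene on chromosome 3 from 106147554 to 106167564, reached 369 ± 71.4 CPM, at least 2150-fold above the control floor (adjusted p 8.03e-06). Acod1, which makes itaconate (chromosome 14, 103046977 to 103056573), reached 103 ± 13.3 CPM, at least 600-fold. The arginine transporter Slc7a2 (chromosome 8, 40862396 to 40922308) rose at least 525-fold, the orphan receptor Gpr141 (chromosome 13, 19749682 to 19824257) at least 468-fold and coagulation factor F10 (chromosome 8, 13037308 to 13056676) at least 427-fold. Among the largest decreases, the sialyltransferase St8sia6 (chromosome 2, 13651021 to 13794064) fell from 54.8 ± 9.99 to 0.272 ± 0.26 CPM, a ratio of 196 with a counting interval of 66.9 to 952. The orphan receptor Gpr165 (chromosome X, 96713441 to 96719388) fell from 47.7 ± 4.38 to 0.264 ± 0.266 CPM, a ratio of 176 with an interval of 60.1 to 856. Cmya5, a muscle-type scaffold gene, and the potassium channel Kcnk12 fell as well, with ratios of 210 (37.4 to 8310) and 123 (21.8 to 4870). The heat shock gene Hspa1b fell (adjusted p 0.0257) from 34.2 ± 35.7 CPM, but this call ended without control replicate 3 or without any 1 of the acute libraries, and also by limma-voom and with the title number as a covariate.

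Antigen presentation, interferon and inflammatory genes rose at the acute phase, in libraries that also held 1870 to 2850 CPM of monocyte genes, against 24.9 to 68 CPM in control libraries. The counts do not assign these rises to a cell type. Of 13 genes for MHC class II and co-stimulation, 10 rose and 2 fell (median 2.18). The number that fell was 1 without control replicate 2 or 3, and 0 without control replicate 1, acute replicate 1 or acute replicate 2. H2-Aa (chromosome 17, 34282744 to 34287823) rose from 0.119 ± 0.11 to 453 ± 57.9 CPM, a ratio of 3910 with a counting interval of 1080 to 32300. The invariant chain Cd74 rose from 18.8 ± 4.59 to 1660 ± 410 CPM and the co-stimulatory receptor Cd40 from 0.463 ± 0.435 to 20.6 ± 3.73 CPM. All 13 MHC class I genes rose (median 1.82), among them the transactivator Nlrc5, from 13 ± 1.22 to 319 ± 19.8 CPM, and the peptide transporter Tap1, from 37.2 ± 4.11 to 360 ± 25.7 CPM. In the type I interferon list 26 of 28 genes rose and 0 fell (median 2.86), with Oasl2 at 118 ± 20.3 against 5.43 ± 2.22 CPM. Of 20 interferon gamma GTPases and targets 19 rose (median 4.71). Nos2, which makes nitric oxide, reached 107 ± 23.4 CPM against 0.0584 ± 0.101, a ratio of 1870 with an interval of 336 to 74100. The GTPase Irgm1 rose from 23 ± 2.19 to 186 ± 7.69 CPM and Cd274, which encodes the checkpoint ligand PD-L1, from 8.41 ± 0.863 to 171 ± 25.4 CPM.

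Of 15 cytokine and chemokine genes 10 rose and 1 fell at the acute phase, with a median of 2.67 and of 2.66 at the floor. Il1b rose from 3.34 ± 0.893 to 74.4 ± 24 CPM, its antagonist Il1rn from 0.273 ± 0.135 to 44.4 ± 12.3 CPM and Cxcl16 from 11.5 ± 0.712 to 90.7 ± 16.9 CPM. Among 20 NF-kB targets and sensors 11 rose and 3 fell, the dismutase Sod2 rising from 7.98 ± 1.79 to 78.1 ± 13.1 CPM, and 7 fell with library totals alone. Among 14 complement genes 8 rose and 4 fell, and only 2 fell without control replicate 3 or acute replicate 1. C3 rose from 2.87 ± 0.665 to 480 ± 15.7 CPM and C4b from 7.92 ± 3.56 to 446 ± 129 CPM. Of 6 Fc receptor genes 3 rose, namely Fcgr2b, Fcgr4 and Fcer1g, the last of which was not called with library totals alone, while Fcgr3 did not pass (adjusted p 0.146).

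Metabolic genes changed as well between control and acute mice, and with monocyte genes at 1870 to 2850 CPM in the acute libraries these changes are not assigned to a cell type either. In the glycolysis list 15 of 16 genes rose and 0 fell (median 1.94), with the pyruvate kinase Pkm at 376 ± 31.7 against 53.2 ± 11.3 CPM and the lactate dehydrogenase Ldha at 147 ± 18.3 against 33.6 ± 1.06 CPM. Of 24 oxidative phosphorylation genes 15 rose, and 7 with library totals alone, the subunit Cox4i1 rising from 14.4 ± 5.09 to 47.1 ± 3.66 CPM. Of 21 cholesterol synthesis genes 13 rose, but 8 without control replicate 1 and 4 with library totals alone. Mvd, an enzyme of the mevalonate pathway, rose from 2.25 ± 0.401 to 16.4 ± 1.73 CPM. Among 15 lipid efflux and storage genes 10 rose and 2 fell, or 1 fell without control replicate 3, acute replicate 2 or acute replicate 3, and the acyltransferase Soat1 rose from 48 ± 2.7 to 112 ± 9.84 CPM. The lysosome list was split, with 11 of 26 genes higher and 5 lower, and its median of 0.12 became -0.44 with library totals alone, where 4 rose and 13 fell. Without acute replicate 1, 3 lysosomal genes fell. Prosaposin, Psap, rose from 1360 ± 110 to 2920 ± 514 CPM. Of 14 growth and repair factors 9 rose and 1 fell, among them the metalloproteinase Mmp14, from 23.9 ± 4.09 to 160 ± 13.5 CPM. In the TGF-beta list 2 of 12 genes rose and 7 fell, including the receptor Tgfbr1, from 1110 ± 44 to 296 ± 27.1 CPM, and its effector Smad3, from 104 ± 6.06 to 28.5 ± 4.32 CPM. Without control replicate 1, 1 TGF-beta gene rose.

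Cell cycle genes also rose at the acute phase, in the libraries in which monocyte genes summed to 1870 to 2850 CPM and neutrophil genes to 128 to 443 CPM, and bulk counts do not show which cells were cycling. Of 17 S phase genes 6 rose and 0 fell, the replication licensing gene Mcm6 rising from 3.47 ± 0.502 to 10.1 ± 0.952 CPM. Of 19 G2 and M phase genes 11 rose, among them the mitotic kinase Plk1, from 0.356 ± 0.0737 to 2.97 ± 0.777 CPM. That number was 6 without control replicate 1 or 2, 5 without control replicate 3, 7 without acute replicate 1 or 3 and 6 with library totals alone. Immediate-early genes, which respond to cell handling, gave 5 higher and 2 lower of 19, and their median of 0.55 became -0.01 with library totals alone. Of these 1 was lower without control replicate 3, 0 without any 1 of the acute libraries and 4 without remission replicate 3. The stress gene Ier3 rose from 0.317 ± 0.279 to 11.8 ± 2.9 CPM.

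Markers of monocytes, neutrophils and T and NK cells were higher in acute than in control libraries. All 15 genes of monocytes and recruited macrophages rose (median 6.43), with summed levels of 1870 to 2850 CPM in acute and 24.9 to 68 CPM in control libraries. Ly6c2 rose at least 379-fold, the chemokine receptor Ccr2 from 2.77 ± 1.16 to 127 ± 33.4 CPM and the arginase Arg1 from 1.69 ± 0.615 to 155 ± 3.42 CPM. Of 3 border macrophage genes 2 rose, the transglutaminase F13a1 from 0.356 ± 0.0737 to 82.3 ± 22.5 CPM, and 4 rose without any 1 library other than acute replicate 2 or 3, where more members passed the filter. Of 5 dendritic cell genes 2 rose and 2 fell, Fscn1 falling from 184 ± 12.7 to 23.9 ± 3.76 CPM, and the list's median changed sign from 0.13 to -0.43 with library totals alone. In this list 1 rose without acute replicate 2, and 4 without any 1 of the remission or chronic libraries. The summed dendritic cell level was 108 to 180 CPM in acute and 218 to 248 CPM in control libraries, where Fscn1 made up most of it. Of 10 neutrophil genes 9 rose (median 9.58, or 6.89 at the floor), including the granule genes Mmp8, at least 103-fold, and Lcn2, at least 171-fold. Of 8 T and NK cell genes 7 rose and 1 fell (median 7.05, or 6.03 at the floor), Cd4 at least 131-fold and Cd3e at least 73.3-fold. The number was 11 without any 1 of the control, remission or chronic libraries.

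Some genes of neural, vascular and erythroid cells passed at the acute phase as well. Of 11 oligodendrocyte and myelin genes 8 rose, but 3 without any 1 of the control libraries or without acute replicate 1, and 5 without acute replicate 3, with library totals alone or with the title number as a covariate. The tight junction gene Cldn11 rose from 0.79 ± 0.403 to 29 ± 12.9 CPM. Of 8 astrocyte genes 4 rose, and 2 without control replicate 1, control replicate 2 or acute replicate 1 or with library totals alone, the folate enzyme Aldh1l1 rising from 2.5 ± 0.88 to 15.3 ± 5.95 CPM. Of 4 neuronal genes 0 passed, with Snap25 at 3.71 ± 0.445 against 4.75 ± 1.87 CPM. Of 4 endothelial and pericyte genes 1 rose, the VEGF receptor Flt1, from 0.961 ± 0.301 to 9.87 ± 0.796 CPM, and 1 fell, Pdgfrb. All 3 erythroid genes rose (median 6.98, or 5.21 at the floor), the heme enzyme Alas2 from 1.77 ± 0.92 to 9.24 ± 1.61 CPM. None of the 4 sex-linked genes tested passed.

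Adjusted over the list alone, the acute counts differed from those above in a few lists. In that adjustment 16 damage-associated genes and 10 myelin genes rose, 10 growth factors rose and 2 fell, and 8 TGF-beta genes, 6 lysosomal genes and 1 interferon gamma target fell. By camera with the preset correlation, the homeostatic list stood lower than other genes (adjusted p 4.21e-22), and the MHC class I (2.83e-11), type I interferon (8.44e-13), interferon gamma (1.77e-13), glycolysis (7.41e-10) and monocyte lists (5.23e-13) stood higher. With the estimated correlation only glycolysis (0.0492) and monocytes (0.0493) held in this comparison, and the homeostatic list had an adjusted p of 0.071. With library totals alone the median log2 fold change over all genes shifted by -0.56 and the share of higher calls fell from 54.3 to 22.8%.

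The comparison of remission with control mice asked which changes were present once signs had eased. It called 1168 genes, 760 higher and 408 lower, of which 466 and 173 changed by more than 2-fold. Without control replicate 2 it called 757 genes, and without control replicate 1 it called 767. Of the 24 damage-associated genes 21 rose and 0 fell (median 3.02). Apoe, the lipid carrier apolipoprotein E, rose from 71.6 ± 31.5 to 4640 ± 422 CPM (log2 fold change 6.03 ± 0.43 SE, adjusted p 8.80e-06), Cd63 from 9.48 ± 0.691 to 73.3 ± 1.04 CPM and Axl from 28.4 ± 11 to 398 ± 79.2 CPM. The growth factor Csf1 rose from 9.47 ± 1.9 to 84.7 ± 11.5 CPM. Igf1, an insulin-like growth factor, rose from 0.0474 ± 0.0821 to 9.79 ± 3.98 CPM, a ratio of 178 with a counting interval of 31.5 to 7090. Of the 24 homeostatic genes 11 fell (median -0.48). Among these the lectin Siglech fell from 344 ± 31.7 to 175 ± 6.93 CPM, the selectin ligand Selplg from 735 ± 81.2 to 355 ± 40 CPM and P2ry12 from 679 ± 93 to 325 ± 11.3 CPM. Tmem119 fell from 972 ± 68.2 to 534 ± 66.3 CPM, and Cx3cr1 did not pass (adjusted p 0.0827).

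The largest increases in remission included Hpse (ENSMUSG00000035273), a heparan sulfate cleaving enzyme on chromosome 5 from 100679484 to 100719716, which reached 32.6 ± 5.29 CPM, at least 192-fold above the control floor in pooled counts (adjusted p 2.42e-08). Gpnmb, a lysosomal glycoprotein (chromosome 6, 49036546 to 49070929), reached 65.2 ± 28.9 CPM, a ratio of 399 with a counting interval of 136 to 1940. Of the 13 MHC class II genes 6 rose and 0 fell (median 1.38). H2-Aa reached 154 ± 38.3 CPM, a ratio of 1380 with an interval of 382 to 11400, H2-Eb1 (chromosome 17, 34305867 to 34316674) 136 ± 29 CPM and Cd74 (chromosome 18, 60803848 to 60812652) 1450 ± 228 CPM. The largest decreases were in Nhs (chromosome X, 161833296 to 162159730), a regulator of the cytoskeleton, from 12.2 ± 2.38 to 0.518 ± 0.31 CPM, and in the prostaglandin-degrading enzyme Hpgd (chromosome 8, 56294585 to 56321043), from 23.5 ± 2.74 to 1.01 ± 0.937 CPM. Gpr165 fell from 47.7 ± 4.38 to 2.31 ± 1.05 CPM and the fructose transporter Slc2a5 (chromosome 4, 150119283 to 150144169) from 40.9 ± 2.8 to 4.53 ± 0.928 CPM. Cmya5 and Kcnk12 fell too, to 1.7 ± 0.835 and 1.03 ± 0.486 CPM.

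Immune and lipid genes changed in remission as well. Of 13 MHC class I genes 8 rose (median 0.92), H2-D1 from 201 ± 11.1 to 1270 ± 184 CPM and Nlrc5 to 107 ± 17.6 CPM. Of 28 type I interferon genes 5 rose, and 3 without control replicate 1 or 3 and 2 without control replicate 2 or remission replicate 3, with Oasl2 at 18.8 ± 3.85 CPM. Of 20 interferon gamma genes 3 rose (median 1.11). Only 1 rose without any 1 of the control libraries, remission replicate 2, remission replicate 3 or chronic replicate 2, and 11 rose without chronic replicate 1 and 5 without chronic replicate 3. Of 15 cytokine genes 6 rose and 1 fell, Cxcl16 reaching 36.9 ± 3.75 CPM and Ccl5 6.61 ± 3.29 CPM against 0.214 ± 0.213. Complement genes gave 4 higher and 1 lower of 14, with C3 at 190 ± 10.8 and C4b at 276 ± 36.4 CPM. Of 15 lipid efflux and storage genes 8 rose (median 1.35), among them the transporter Abcg1, from 20.1 ± 1.85 to 81.4 ± 10.3 CPM, and Soat1, to 110 ± 5.27 CPM. Of 26 lysosomal genes 15 rose and 0 fell (median 0.64, or 0.58 at the floor), and 8 with library totals alone, the protease Ctsb rising from 598 ± 87.6 to 1650 ± 183 CPM.

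Glycolysis gave 9 higher and 1 lower of 16 genes in remission, with 5 higher without control replicate 2 or with library totals alone. Aldoa, an aldolase, rose from 40 ± 1.74 to 74.8 ± 7.96 CPM. Of 14 growth factors 6 rose and 1 fell, Spp1, which encodes osteopontin, rising from 2.48 ± 0.788 to 43.5 ± 25.8 CPM. None of 21 cholesterol synthesis, 24 oxidative phosphorylation, 6 Fc receptor, 17 S phase and 19 G2 and M phase genes passed. The medians of both cell cycle lists were negative, at -0.33 and -0.82. Of 20 NF-kB genes 4 rose and 1 fell, with Tlr2 at 158 ± 23.3 against 79.1 ± 3.59 CPM, and the median of 0.18 became -0.07 with library totals alone. The number of NF-kB genes that rose was 2 without control replicate 1, control replicate 3 or remission replicate 3, and 1 without control replicate 2. Of 12 TGF-beta genes 1 fell. Of 19 immediate-early genes 4 rose (median 0.98), the stress factor Atf3 reaching 22.3 ± 6.65 CPM, and the median was -0.48 without remission replicate 3. Of them 2 rose without control replicate 1, control replicate 2 or remission replicate 3, and 1 without control replicate 3.

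Some markers of other cells passed between remission and control. Of 15 monocyte genes 2 rose (median 0.42, or 0.27 at the floor), namely Ly6i, a Ly-6 family gene, at 1.73 ± 1.11 CPM, and the matrix gene Emilin2, at 11.8 ± 1.83 CPM. The call of Emilin2 ended without control replicate 1 or remission replicate 1, which left 1 monocyte gene. The summed monocyte level was 43.2 to 53.5 CPM. No neutrophil, border macrophage or myelin gene passed. All 3 remission libraries nevertheless lay above the control range in the summed level of neutrophil genes (1.06 to 62.2 against 0.35 to 0.647 CPM), astrocyte genes (101 to 221 against 64.9 to 81.5 CPM), endothelial and pericyte genes (25 to 33.2 against 14.5 to 15.9 CPM) and erythroid genes (4.25 to 38.9 against 1.08 to 3.13 CPM). They lay below it in T and NK cell genes (6.37 to 10.9 against 25.2 to 39.1 CPM) and dendritic cell genes (116 to 143 against 218 to 248 CPM). The summed myelin level reached 746 CPM in remission replicate 1, against 72.7 and 151 CPM in the other replicates and 92.7 to 114 CPM in control libraries. The receptor Il7r carried the T and NK cell fall, from 28.5 ± 6.65 to 5.76 ± 1.14 CPM. Of 5 dendritic cell genes Fscn1 carried the fall, from 184 ± 12.7 to 82.5 ± 8.14 CPM. Flt3 rose from 0.593 ± 0.351 to 2.7 ± 1.53 CPM, a call that ended without control replicate 2, control replicate 3 or remission replicate 1. Of 3 erythroid genes Hba-a1 rose (adjusted p 0.0189), a call that ended without any 1 of the control libraries or remission replicate 1. The astrocyte gene Aldh1l1 rose from 2.5 ± 0.88 to 6.25 ± 1.05 CPM and Flt1 from 0.961 ± 0.301 to 12.8 ± 5.37 CPM. The call of Aldh1l1 ended without control replicate 1, control replicate 3 or remission replicate 1. Slc1a3, also of astrocytes, rose from 41.2 ± 5.61 to 91.9 ± 32.6 CPM, a call that ended without any 1 of the control or acute libraries, remission replicate 1, remission replicate 2 or chronic replicate 2. The astrocyte median became -0.18 without remission replicate 1, and the endothelial median went from 0.22 to -0.05 with library totals alone.

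Adjusted over the list alone, 14 homeostatic genes fell in remission, and 8 MHC class II, 9 MHC class I, 6 type I interferon, 7 cytokine, 11 lipid, 10 glycolysis, 7 growth factor and 3 erythroid genes rose. By camera the damage-associated (adjusted p 5.89e-35), lipid (1.08e-14), glycolysis (1.28e-06), MHC class I (2.94e-12) and MHC class II lists (2.23e-11) stood higher and the homeostatic list lower (2.90e-11). The first 3 of these held with the estimated correlation, at 0.0492 for damage-associated and lipid genes and 0.0493 for glycolysis, and no other list did in this comparison. Both cell cycle lists stood lower with the preset correlation (0.0375 and 0.00769) and did not hold with the estimated correlation (0.584 and 0.583). The median over all genes shifted by -0.25 with library totals alone, and the share of higher calls fell from 65.1 to 32.6%.

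The comparison of chronic with control mice asked which changes were present late in disease. It called 1848 genes, 1200 higher and 648 lower, 746 and 249 of them by more than 2-fold. It called 1216 genes without control replicate 2 and 3241 with library totals alone. Of the 24 damage-associated genes 22 rose and 0 fell (median 3.18). Apoe rose from 71.6 ± 31.5 to 4130 ± 1530 CPM (log2 fold change 5.86 ± 0.43 SE, adjusted p 6.32e-06), Cd63 to 85.3 ± 10.5 CPM, Axl to 416 ± 81.4 CPM and Csf1 to 81.5 ± 22 CPM. Igf1 reached 18.7 ± 6.43 CPM, a ratio of 337 with a counting interval of 59.9 to 13300. Of the 24 homeostatic genes 11 fell (median -0.56), and 17 with library totals alone. P2ry12 fell from 679 ± 93 to 261 ± 32.4 CPM, Selplg from 735 ± 81.2 to 346 ± 27.2 CPM, Siglech to 160 ± 13.8 CPM and Tmem119 to 587 ± 26.1 CPM. Cx3cr1 fell from 2190 ± 118 to 1390 ± 185 CPM, a call that ended without control replicate 2 or chronic replicate 1.

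The leading increases in chronic mice again included Hpse, at 39.8 ± 14 CPM and at least 234-fold, Gpnmb, at 164 ± 89.9 CPM with a ratio of 962 (counting interval 329 to 4670), and H2-Aa, at 317 ± 157 CPM with a ratio of 2900 (804 to 24000). Cxcl13 (ENSMUSG00000023078), a B cell attracting chemokine on chromosome 5 from 95956951 to 95961068, reached 20.6 ± 4.75 CPM, at least 118-fold (adjusted p 8.00e-09). Hpgd fell from 23.5 ± 2.74 to 0.06 ± 0.104 CPM, a ratio of 325 with an interval of 58 to 12900. Sema4b, a semaphorin (chromosome 7, 80186841 to 80226527), fell from 24.8 ± 3.02 to 1.39 ± 0.391 CPM, the zinc finger gene Zfp827 (chromosome 8, 79028437 to 79193766) from 12.2 ± 1.68 to 0.656 ± 0.532 CPM and the basement membrane gene Nid2 (chromosome 14, 19751265 to 19811787) from 10.5 ± 2.62 to 0.803 ± 0.699 CPM. Gpr165 fell to 1.21 ± 1.17 and Nhs to 0.496 ± 0.672 CPM.

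Antigen presentation and interferon gamma genes rose in chronic mice. Of 13 MHC class II genes 11 rose and 1 fell (median 1.93), Cd74 reaching 2100 ± 925 and H2-Ab1 354 ± 155 CPM. Of 13 MHC class I genes 12 rose (median 1.52), Nlrc5 reaching 198 ± 48.7 and Tap1 156 ± 51.4 CPM. Of 28 type I interferon genes 8 rose (median 0.90), and 5 without control replicate 2. Of 20 interferon gamma genes 14 rose (median 2.16), with 9 without control replicate 1 and 8 in the fit of 6 libraries. Irgm1 reached 83.5 ± 31.1 and Cd274 40.6 ± 18.4 CPM. The 3 chronic libraries differed in this list, with summed levels of 573, 1160 and 1550 CPM against 523 to 546 CPM in control libraries. Complement gave 9 higher and 0 lower of 14 genes (median 0.91), C4b rising from 7.92 ± 3.56 to 758 ± 147 CPM and the anaphylatoxin receptor C3ar1 from 56.8 ± 12.7 to 135 ± 5.18 CPM. Of 15 cytokine genes 6 rose and 1 fell, Cxcl14 from 1.68 ± 1.17 to 13.5 ± 5.2 CPM. Of 6 Fc receptor genes 2 rose, Fcgr4 from 2.11 ± 0.72 to 14.4 ± 7.69 CPM, and the list's median of 0.22 became -0.16 with library totals alone.

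Of 15 lipid efflux and storage genes 11 rose in chronic mice (median 1.53), Abcg1 reaching 107 ± 40.9 CPM and the cholesterol carrier Npc2 178 ± 17.6 against 90.7 ± 4.98 CPM. Of 26 lysosomal genes 18 rose and 0 fell (median 0.76), and 10 with library totals alone, Ctsb reaching 1840 ± 442 and the cathepsin Ctsz 670 ± 126 CPM. Of 16 glycolysis genes 12 rose, Pkm from 53.2 ± 11.3 to 189 ± 23.6 CPM. Of 24 oxidative phosphorylation genes 4 rose, with 1 without control replicate 1 or with library totals alone and 2 without chronic replicate 3. Of 14 growth factors 9 rose and 1 fell, Grn, which encodes progranulin, rising from 391 ± 36.5 to 973 ± 182 CPM. Of 12 TGF-beta genes 4 fell, Tgfbr1 to 678 ± 116 CPM, with 2 without control replicate 2 and 7 with library totals alone. None of 21 cholesterol synthesis genes passed. Of 20 NF-kB genes 3 rose and 2 fell, with 1 higher without control replicate 2 and 1 lower without control replicate 2, control replicate 3, chronic replicate 1 or chronic replicate 3, and the inflammasome sensor Nlrp3 fell from 88.9 ± 13.1 to 51.6 ± 11.8 CPM. The NF-kB median of 0.30 became -0.06 with library totals alone. The immediate-early median of 0.02 became -0.33 with library totals alone and was below 0 with DESeq2 too.

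Cell cycle genes were higher in chronic than in control mice, with 7 of 17 S phase genes (median 0.94) and 12 of 19 G2 and M phase genes (median 2.19) rising and 0 falling. The cyclin Ccna2 rose from 1.77 ± 0.302 to 8.39 ± 6.45 CPM and Mcm6 from 3.47 ± 0.502 to 13.8 ± 8.9 CPM. Chronic replicate 3 set much of this level. The summed G2 and M phase level was 448 CPM in it, against 97.2 and 84.6 CPM in the other chronic libraries and 32.2 to 49.1 CPM in control libraries. Without chronic replicate 3, 1 S phase gene and 3 G2 and M phase genes rose. The S phase number was 2, 3 and 1 without control replicates 1, 2 and 3, and 11 without chronic replicate 1. The G2 and M phase number was 4, 6 and 4 without control replicates 1, 2 and 3, and 3 in the fit of 6 libraries.

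**Figure D3:**
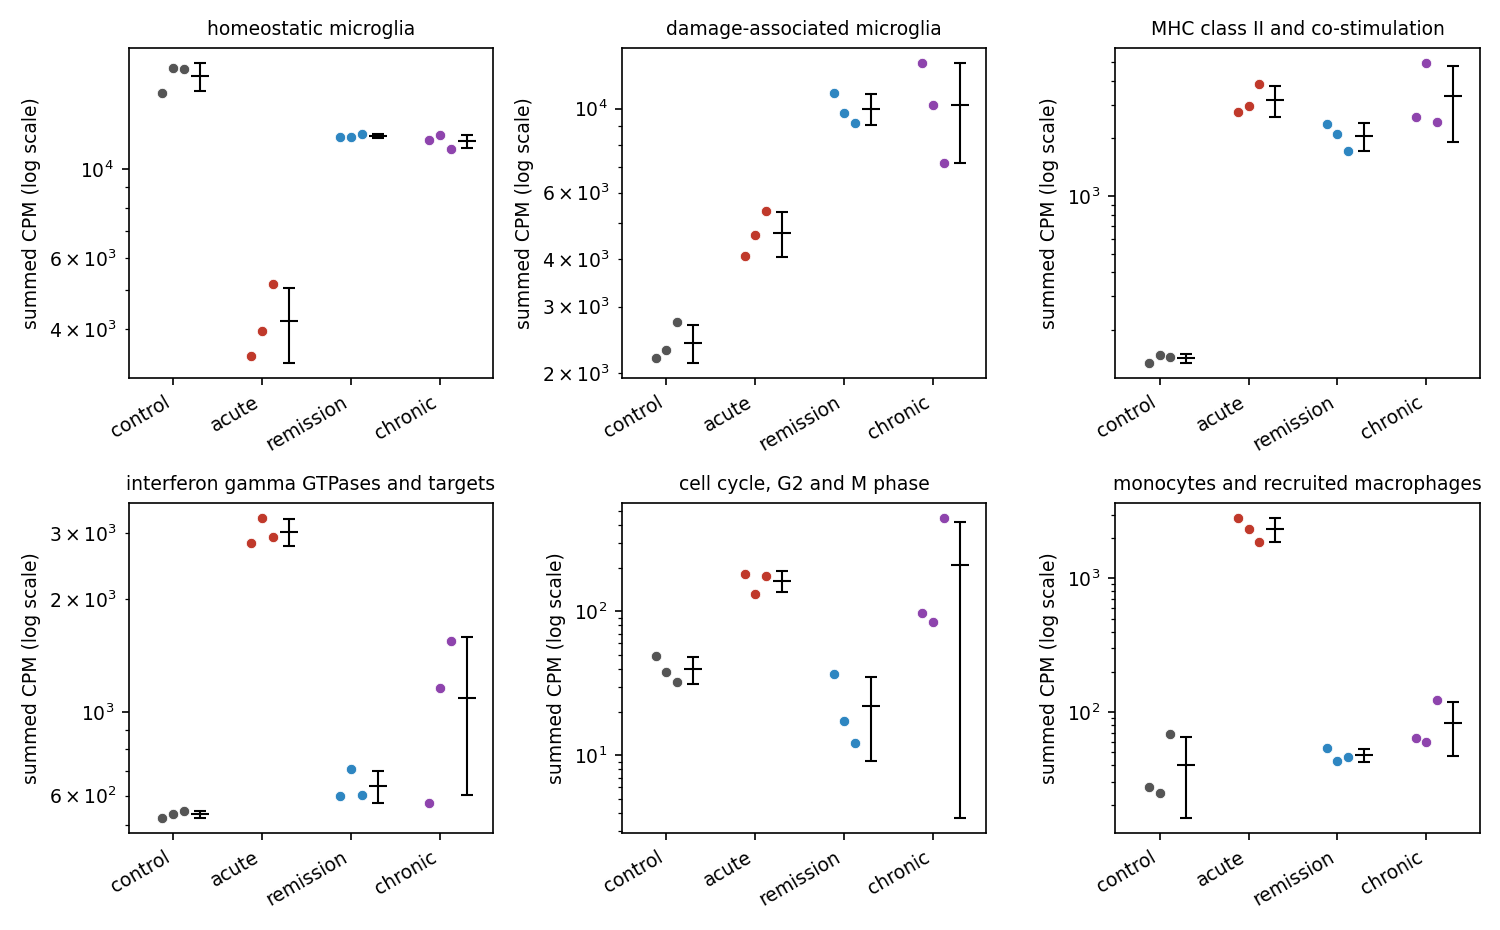
Each point is the summed level of a fixed list in 1 library, in CPM on a log scale, for 6 lists and the 4 groups, with the mean and SD of 3 libraries beside the points. The G2 and M phase level of 448 CPM belongs to chronic replicate 3, and the monocyte level is 1870 to 2850 CPM in acute and at most 123 CPM in all other libraries.

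Between chronic and control mice some markers of other cells passed. All 3 chronic libraries lay below the control range in the summed level of T and NK cells (4.54 to 10.5 against 25.2 to 39.1 CPM), dendritic cells (115 to 203 against 218 to 248 CPM) and myelin genes (84.9 to 85.2 against 92.7 to 114 CPM). They lay above it in astrocytes (116 to 205 against 64.9 to 81.5 CPM) and endothelial cells and pericytes (36.2 to 69.1 against 14.5 to 15.9 CPM). Single genes carried most of this. Il7r, at 28.5 CPM in control, carried the T and NK cell difference. Slc1a3 carried the astrocyte and Flt1 the endothelial difference, and Fscn1 made up most of the control dendritic cell level. Here and in remission, sums carried by single genes do not show a change in a cell type. Of 15 monocyte genes 2 rose and 1 fell (median 0.91, or 0.32 at the floor), Emilin2 from 1.83 ± 0.508 to 34.6 ± 22.4 CPM, with summed levels of 60 to 123 CPM. Without control replicate 3, 4 monocyte genes rose. Ccr2 fell from 2.77 ± 1.16 to 0.833 ± 0.292 CPM, a call that ended without control replicate 1, control replicate 3 or any 1 of the chronic libraries. Il7r fell to 6.01 ± 3.46 CPM. No neutrophil, myelin, neuronal or erythroid gene passed. Of 8 astrocyte genes 2 rose, Aldh1l1 to 9.53 ± 1.38 CPM and the glutamate transporter Slc1a3 from 41.2 ± 5.61 to 127 ± 52.7 CPM, and the median of 0.14 became -0.24 with library totals alone. Flt1 rose from 0.961 ± 0.301 to 38.6 ± 18.1 CPM and the adhesion gene Pecam1 fell from 3.36 ± 0.527 to 0.536 ± 0.33 CPM. The endothelial median went from 0.33 to -0.04 with library totals alone.

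Adjusted over the list alone, 14 homeostatic genes fell and 1 rose in chronic mice, and 23 damage-associated, 16 interferon gamma, 10 type I interferon, 14 S phase, 18 G2 and M phase and 20 lysosomal genes rose. By camera the damage-associated (adjusted p 1.17e-30), MHC class I (1.88e-18), MHC class II (1.08e-14), lipid (1.11e-12), glycolysis (4.60e-11) and growth factor lists (5.55e-07) stood higher, and these 6 held with the estimated correlation at 0.0492 or 0.0493. The homeostatic list (6.64e-09) and the G2 and M phase list (3.29e-07) did not hold, at 0.244 and 0.309. With library totals alone the median over all genes shifted by -0.36 and the share of higher calls fell from 64.9 to 21.7%.

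**Figure D4:**
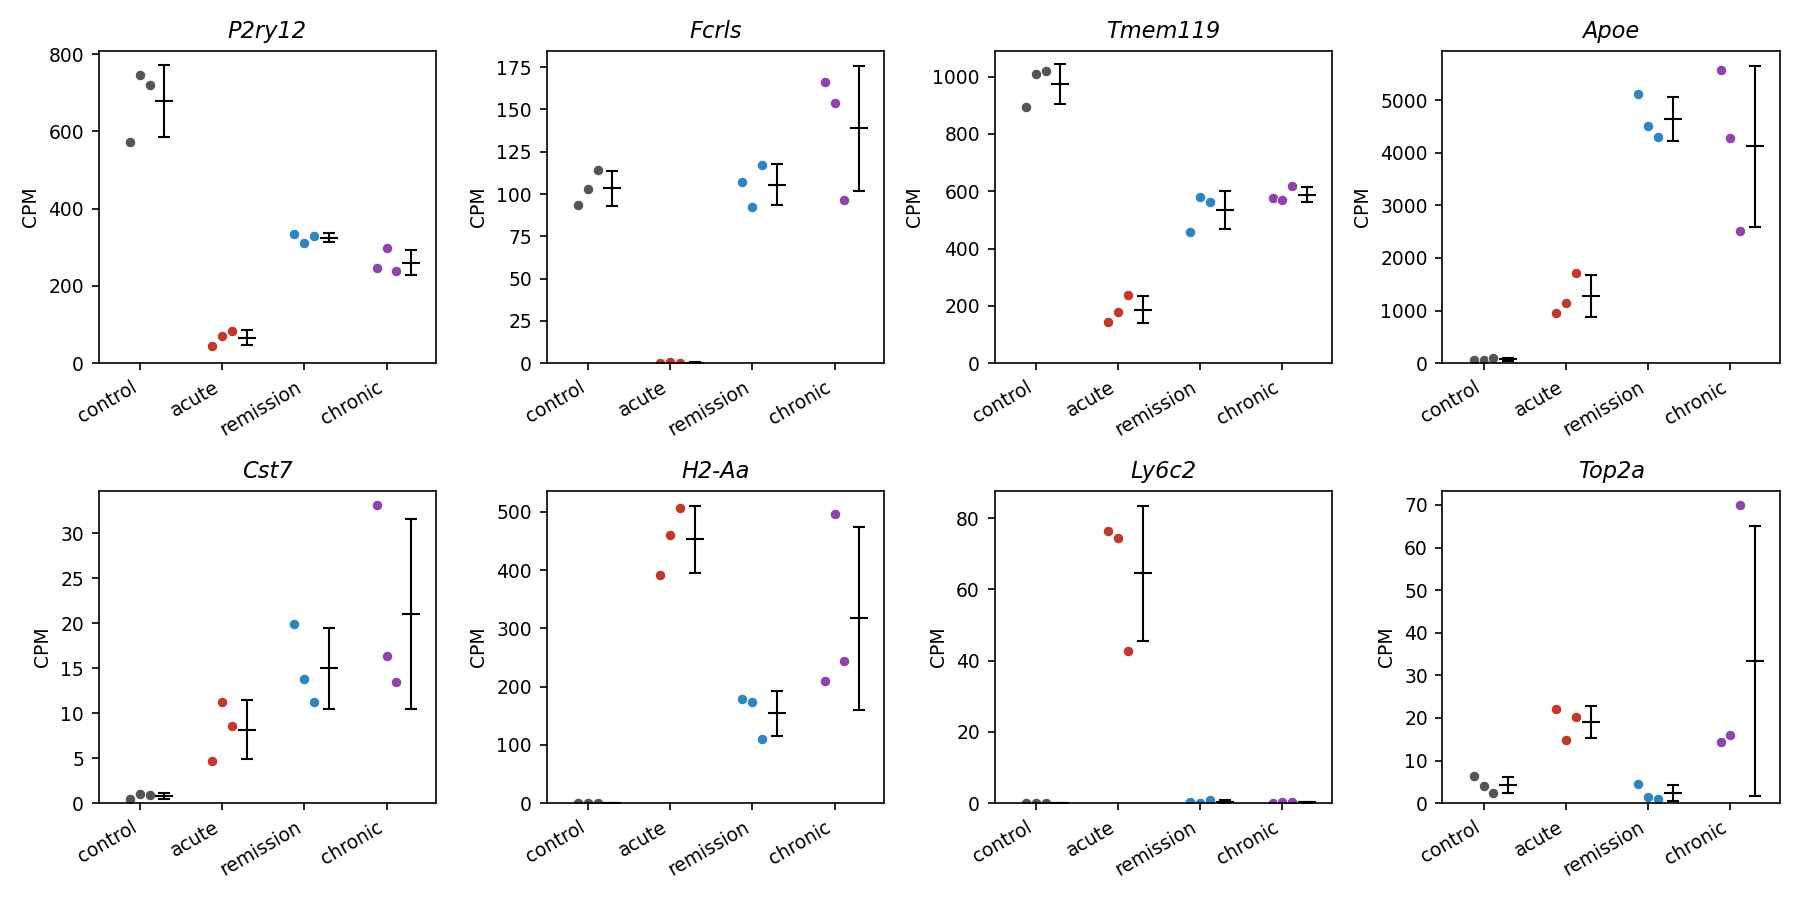
Points give the level of a gene in CPM in each library of the 4 groups, with the mean and SD of 3 libraries beside them, and an SD that would pass 0 ends there. P2ry12 stood at 679 ± 93 CPM in control and 66.5 ± 18.8 CPM in acute mice, Fcrls at 103 ± 10 and 0.365 ± 0.404 CPM, and Apoe at 4640 ± 422 CPM in remission.

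Remission against acute mice gave 4634 called genes, 2205 higher and 2429 lower in remission. Here and for chronic mice, cell mixture and microglial change are not separated. All 24 homeostatic genes were higher (median 1.64), Fcrls at 106 ± 12.3 against 0.365 ± 0.404 CPM (adjusted p 1.26e-10), Olfml3 (chromosome 3, 103722222 to 103738001) at 152 ± 30.5 against 3.8 ± 1.64 CPM and Gpr34 at 164 ± 14.7 against 21.3 ± 4.84 CPM. Of the 24 damage-associated genes 13 were higher and 4 lower, the lipid receptor Trem2 at 420 ± 40.8 against 90.9 ± 26.8 CPM and Lgals3 at 6.52 ± 2.24 against 128 ± 19.9 CPM. The laminin Lama3 (chromosome 18, 12333819 to 12583013) reached 11.8 ± 3.46 against 0.472 ± 0.362 CPM and the cilia gene Cfap74 (chromosome 4, 155409190 to 155466823) 75.8 ± 8.91 against 3.22 ± 1.22 CPM. Without a count in remission, F13a1 (chromosome 13, 36867178 to 37050244) was at least 399-fold lower, F10 at least 354-fold, the interferon-inducible gene Slfn4 (chromosome 11, 83175186 to 83190216) at least 192-fold, the lectin Clec12a (chromosome 6, 129342691 to 129365303) at least 133-fold and the myeloid receptor Trem1 (chromosome 17, 48232768 to 48246924) at least 118-fold. Lower in remission were also 8 of 13 MHC class II genes, 12 of 13 MHC class I genes, 26 of 28 type I interferon genes and 19 of 20 interferon gamma genes (median -3.51). Nos2 stood at 0.403 ± 0.157 against 107 ± 23.4 CPM and Tap1 at 94.6 ± 6.25 against 360 ± 25.7 CPM.

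Of the other lists between remission and acute mice, glycolysis gave 13 of 16 genes lower, Ldha at 45.7 ± 1.96 against 147 ± 18.3 CPM, and cytokines 8 of 15 lower and 2 higher, Il1b at 2.99 ± 1.14 against 74.4 ± 24 CPM. Only 1 cytokine gene was higher without acute replicate 2 or remission replicate 2. Of 24 oxidative phosphorylation genes 13 were lower, and 6 with library totals alone, and of 21 cholesterol synthesis genes 12, and 7 with library totals alone. Of 26 lysosomal genes 13 were higher and 3 lower, the cathepsin Ctsd at 1540 ± 67.4 against 574 ± 132 CPM. All 15 monocyte genes (median -6.33), all 8 T and NK cell genes and 7 of 10 neutrophil genes were lower, Ccr2 at 1.35 ± 0.592 against 127 ± 33.4 CPM and Cd3e at 0.0615 ± 0.107 against 12.5 ± 3.61 CPM. The neutrophil number was 4 without acute replicate 2 and 3 with DESeq2. Of 11 myelin genes 1 was lower, but 9 were lower without remission replicate 1. Of 8 astrocyte genes 2 were lower, but 6 without remission replicate 1 and 1 without any other library except chronic replicate 1. Of 19 G2 and M phase genes 15 were lower. By camera glycolysis (adjusted p 2.23e-08) and monocytes (4.43e-15) held with the estimated correlation, each at 0.0492. The NF-kB median of -0.30 became 0.01 with library totals alone, the median over all genes shifted by 0.31 and the share of higher calls rose from 47.6 to 71.2%.

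Chronic against acute mice gave 3610 called genes, 1670 higher and 1940 lower, and 2402 with the title number as a covariate. All 24 homeostatic genes were higher (median 1.66), Fcrls at 139 ± 37.1 and Olfml3 at 209 ± 28.7 CPM. Of the 24 damage-associated genes 16 were higher and 4 lower, Igf1 (chromosome 10, 87858265 to 87937042) at 18.7 ± 6.43 against 0.657 ± 0.475 CPM. The kinase Ripk4 (chromosome 16, 97741933 to 97763787) stood at 17.1 ± 7.92 against 0.284 ± 0.297 CPM, a ratio of 63.8 with a counting interval of 21.6 to 312. F10 was at least 341-fold lower, the decoy receptor Il1r2 (chromosome 1, 40074079 to 40125231) at least 159-fold, the protease Adam19 (chromosome 11, 46055992 to 46147343) at least 140-fold and the cytokine receptor Il18r1 (chromosome 1, 40465552 to 40500854) at least 91.8-fold. Of 14 complement genes 7 were higher and 3 lower, the C1q subunit C1qb at 1010 ± 66.8 against 372 ± 91.2 CPM. Of 26 lysosomal genes 15 were higher and 1 lower.

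Lower in chronic than in acute mice were 24 of 28 type I interferon genes, or 15 with the title number as a covariate, 16 of 20 interferon gamma genes, 13 of 16 glycolysis genes and 12 of 21 cholesterol synthesis genes, or 7 with that covariate. The peptide transporter Tap1 stood at 156 ± 51.4 against 360 ± 25.7 CPM, and 8 of 13 MHC class I genes were lower, or 5 with that covariate or without chronic replicate 2. Of 13 MHC class II genes 1 was higher and 1 lower, and 4 were lower without chronic replicate 2. Of 24 oxidative phosphorylation genes 6 were lower, and 3 with library totals alone, with the covariate or without acute replicate 1, acute replicate 2, chronic replicate 1 or chronic replicate 2. All 15 monocyte genes (median -6.39), all 8 T and NK cell genes, 8 of 10 neutrophil genes and 8 of 11 myelin genes were lower. The neutrophil number was 5 without chronic replicate 2 or with the covariate, and the myelin number was 5, 4 and 3 without acute replicate 1, chronic replicate 1 and chronic replicate 2. Ccr2 stood at 0.833 ± 0.292 against 127 ± 33.4 CPM and Cldn11 at 0.495 ± 0.429 against 29 ± 12.9 CPM. Of 15 cytokine genes 3 were higher, or 1 without chronic replicate 2, and 7 lower. By camera only monocytes (adjusted p 2.04e-17) held with the estimated correlation, at 0.0492. The Fc receptor median of -0.12 and the growth factor median of -0.14 became 0.06 and 0.06 with library totals alone, the median over all genes shifted by 0.20 and the share of higher calls rose from 46.3 to 64.4%.

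The comparison of chronic with remission mice asked how the later stages differ, and it called the fewest genes of the 6. It called 151 genes, 118 higher and 33 lower, and DESeq2 called 385, limma-voom 54 and the fit of 6 libraries 26. Single libraries moved the number too, to 65 without remission replicate 1, 283 without remission replicate 2, 17 without remission replicate 3, 272 and 270 without chronic replicates 1 and 2, 50 without chronic replicate 3, and 94 without control replicate 2. Ripk4 (ENSMUSG00000005251) rose from 0.503 ± 0.48 to 17.1 ± 7.92 CPM (log2 fold change 4.90 ± 0.58 SE, adjusted p 5.96e-04), Cxcl13 from 3.14 ± 0.902 to 20.6 ± 4.75 CPM (5.96e-04) and Ldha from 45.7 ± 1.96 to 89.3 ± 8.63 CPM (9.09e-04). Mcm6 (chromosome 1, 128331590 to 128359664) rose from 1.61 ± 0.473 to 13.8 ± 8.9 CPM and Irgm1 from 32.5 ± 3.33 to 83.5 ± 31.1 CPM. These 5 calls ended in no fit without a single library. The interferon regulator Irf1 rose from 41.3 ± 4.16 to 94.8 ± 30.8 CPM, Slc2a5 from 4.53 ± 0.928 to 17.5 ± 9.48 CPM and the anaphylatoxin receptor C5ar1 from 10.6 ± 2.36 to 28.7 ± 12 CPM, with the same result.

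Calls of other genes between chronic and remission mice rested on single libraries. Pkm, at 189 ± 23.6 against 103 ± 7.66 CPM, and Nlrc5, at 198 ± 48.7 against 107 ± 17.6 CPM, lost their calls without remission replicate 3. The serine protease Htra3 (chromosome 5, 35652023 to 35679782), at 17.4 ± 12.8 against 1.83 ± 0.989 CPM, did so as well. C4b, at 758 ± 147 against 276 ± 36.4 CPM, lost its call without remission replicate 1, remission replicate 3 or chronic replicate 3. The replication regulator Uhrf1 (chromosome 17, 56303321 to 56323486), at 13.5 ± 12.7 against 0.548 ± 0.366 CPM, lost it without remission replicate 1 or 3. Among genes lower in chronic mice, the Notch pathway gene Asb2 (chromosome 12, 103321142 to 103356001) stood at 15.9 ± 1.57 against 33 ± 10.3 CPM and lost its call without remission replicate 1, remission replicate 3, chronic replicate 1 or chronic replicate 3.

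Of 19 G2 and M phase genes 9 were higher in chronic than in remission mice (median 3.01), Ccna2 at 8.39 ± 6.45 against 1.48 ± 0.364 CPM, a call that ended without remission replicate 3 or chronic replicate 3. The number was 1 without remission replicate 1, 5 without remission replicate 2, 0 without remission replicate 3, 14 without chronic replicate 2, 3 without chronic replicate 3, 14 with DESeq2 and 0 with limma-voom or the fit of 6 libraries. Of 17 S phase genes 3 were higher (median 1.29), with 1 without remission replicate 3 and 6 without chronic replicate 1 or 2. Of 20 interferon gamma genes 3 were higher (median 1.40), and 15 without chronic replicate 1. Of 13 MHC class I genes 4 were higher (median 0.60), 0 without remission replicate 3, 1 without chronic replicate 3, 7 without chronic replicate 1 and 2 without control replicate 2, acute replicate 2, acute replicate 3 or remission replicate 1. Glycolysis gave 3 of 16, with 1 without remission replicate 3. MHC class II gave 2 of 13, with 0 without remission replicate 3 or chronic replicate 3 and 1 without any other library except remission replicate 2 or chronic replicate 1. Complement gave 2 of 14 higher, or 4 without acute replicate 1 or chronic replicate 2 and 1 without remission replicate 1, remission replicate 3 or chronic replicate 3. No damage-associated gene passed, and Slc2a5 was the only homeostatic gene that did. Adjusted over the list alone, 18 G2 and M phase, 14 S phase, 14 interferon gamma, 11 MHC class I, 8 MHC class II, 8 complement, 8 glycolysis and 6 growth factor genes were higher and 7 myelin genes lower.

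By camera the G2 and M phase (adjusted p 1.44e-21), S phase (5.42e-14), interferon gamma (1.10e-11) and MHC class I lists (8.23e-10) stood higher in chronic than in remission mice and the myelin list lower (2.22e-06). With the estimated correlation only glycolysis held, at 0.0493, and both cell cycle lists and MHC class I had 0.0931. The median over all genes shifted by -0.12 with library totals alone, the share of higher calls fell from 78.1 to 61.4%, and without remission replicate 2 that share was 42.4%. Over all 6 comparisons 111 of the 186 list tests passed with the preset correlation, 15 with the estimated correlation and 105 with fry.

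Changes against the control mice overlapped between phases. Higher in all 3 phases were 505 genes and lower in all 3 were 232, while 1925 were called higher and 1916 lower in the acute phase and not called in that direction in the others, which does not show that they were unchanged there. Remission and chronic mice shared 606 higher genes, against 72.7 for independent lists and 0.04 in simulations of unchanged groups against the same controls, which hold almost no calls, and 266 lower genes, against 21.1 and 0.03. Acute and remission mice shared 579 higher genes (180 if independent, 0.01 simulated) and 298 lower genes (81.6 and 0.02). Acute and chronic mice shared 978 higher genes (285 and 0.03) and 528 lower genes (130 and 0). Across genes, Pearson's r of log2 fold changes was 0.665 between remission and chronic mice against 0.479 in 100 simulations, 0.658 against 0.469 for acute and remission mice, and 0.623 against 0.469 for acute and chronic mice. The covariance was 0.556 between remission and chronic mice against 0.0552 simulated, a difference of 0.501. The difference was 0.909 for acute and remission mice, and 0.938 for acute and chronic mice. The 3 control libraries were not split, since 1 part would hold a single library, so part of the excess in shared calls may come from the shared controls.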

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

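The direct comparisons between phases had been planned, whereas the counts of genes with opposite calls and the tests of explanations in this part were chosen only after the results had been seen.

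Some genes moved in opposite directions against control mice in different phases, and the phases also differed in their direct comparison. Of these, 21 genes were higher in acute and lower in remission mice, 19 were lower in acute and higher in remission mice, 13 were higher in acute and lower in chronic mice, and 24 were lower in acute and higher in chronic mice. Many of these calls rested on the scaling. With library totals alone 7 of the 21, 4 of the 19, 9 of the 13 and 8 of the 24 kept both calls, and with DESeq2 20, 16, 12 and 22 did. The comparisons share their control libraries, so an extreme control value would move both phases the same way and not apart.

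The genes named here were chosen after their values were seen. The lipid-modifying enzyme gene Smpdl3b rose at the acute phase (log2 fold change 2.29) and fell in remission (-3.10) and in chronic mice (-2.58). Its calls ended in none of the alternatives run. Palm, which encodes a membrane protein of many tissues, rose at the acute phase (3.12) and fell in chronic mice (-3.81). The protease inhibitor Serpine2 fell at the acute phase (-3.04) and rose in remission (0.88) and chronic mice (0.89). The cell cycle inhibitor Cdkn1a rose at the acute phase (1.36) and fell in remission (-1.61), and Cd83, a surface protein of activated cells, fell (-1.28) and then rose (0.97). The complement gene C1qb fell at the acute phase (-0.65) and rose in chronic mice (0.79), a rise that was not called with library totals alone.

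A mixture that changes between phases is a candidate explanation for such pairs, since all 15 monocyte genes were higher at the acute phase. Of the genes above, Ccr2 is itself a monocyte marker. It rose from 2.77 ± 1.16 to 127 ± 33.4 CPM at the acute phase and fell to 0.833 ± 0.292 CPM in chronic mice, a fall that was not called without control replicate 1, control replicate 3, any 1 of the chronic libraries, or with limma-voom. Whether Serpine2 and C1qb changed within microglia or were diluted at the acute phase stays open, because bulk libraries hold no levels per cell.

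The cell cycle lists stood on opposite sides of other genes in different phases with the preset correlation. The G2 and M phase list stood higher than other genes in acute and lower in remission mice, each against control, with an adjusted p of 2.37e-06 for the direct comparison. The S phase list stood lower in remission and higher in chronic mice (5.42e-14 directly), and so did the G2 and M phase list (1.44e-21 directly). With the estimated correlation the 3 direct tests had adjusted p of 0.341, 0.0931 and 0.0931, so none of them passed. Nor did the tests against control with that correlation, at 0.532 for G2 and M phase in acute mice, 0.584 for S phase and 0.583 for G2 and M phase in remission, and 0.309 for both lists in chronic mice, so the opposite directions stay open. In remission 0 members of either list were called by edgeR against control mice, although 2734 genes over the whole comparison had an unadjusted p under 0.05 and 1248 were called there by DESeq2 and 1363 by limma-voom.

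Cell cycle genes were higher in chronic mice than in remission, with 9 of 19 G2 and M phase genes called and 448 CPM of summed level in chronic replicate 3. A single animal as the whole cause is argued against by the other chronic libraries, the lower of which held 84.6 CPM, above the highest control or remission library at 49.1 CPM. Recruited cycling cells like those of the acute libraries are argued against too, since the highest chronic ratio of monocyte to G2 and M phase levels was 0.709 and the lowest acute ratio 10.6. With the number at the end of the titles as a covariate the median was 2.95 in place of 3.01 and 7 members were called, which argues against that number as the whole cause. A larger share of dividing microglia in chronic disease may explain the pattern. The number of genes called was not stable, however, with 3 without chronic replicate 3. It was 1, 5 and 0 without remission replicates 1, 2 and 3, and each of these fits holds fewer libraries.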

How the results depend on the processing

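Leaving out remission replicates 1 and 3 together, and leaving out the 6 features with the most counts with all mitochondrially encoded genes, were tests chosen only after the results had been seen, and the other alternatives here were planned. Without both of these remission replicates 1 remission library is left, so no calls from that fit are given.

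The number of genes called between chronic and remission mice, 151, depended most on the processing. DESeq2 called 385, limma-voom 54, the fit without a filter 828, the strict filter 98 and the fit of only the 6 libraries compared 26. Without remission replicates 1 and 3 edgeR called 0, with 1161 genes at an unadjusted p under 0.05. Leaving out each library in turn gave 17 to 283 genes, with the lowest number without remission replicate 3 and the highest without remission replicate 2, and 65, 50, 272, 270 and 94 without remission replicate 1, chronic replicate 3, chronic replicate 1, chronic replicate 2 and control replicate 2. The share of higher genes was 78.1%, against 58.5% without a filter, 67.3% with the strict filter, 88.5% with 6 libraries and 61.4% with library totals alone. Without remission replicate 2 it was 42.4%. The cause was not tested.

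Between remission and control mice 1168 genes were called, 518 without remission replicates 1 and 3, and 757 to 1312 without each library in turn, the lowest without control replicate 2. Control replicate 1 gave 767 when left out. Between chronic and control mice 1848 were called, 3241 with library totals alone and 1216 without control replicate 2 to 1927 without remission replicate 1. Between chronic and acute mice 3610 were called, and 2402 with the title number as a covariate. All chronic libraries carry the title number 1, so the covariate rests on the other groups. The numbers for acute against control, remission against acute and any difference among the groups stayed within 1.5 times of 5487, 4634 and 5517 in the alternatives run.

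Scaling by library totals moved the split of higher and lower genes. Those totals include the 6 features with the most counts, at a mean of 53.6% of counts in control and 63.2% in acute libraries. With library totals alone 22.8% of calls were higher in place of 54.3% for acute against control, 32.6 in place of 65.1% for remission against control and 21.7 in place of 64.9% for chronic against control. For remission against acute it was 71.2 in place of 47.6%, and for chronic against acute 64.4 in place of 46.3%. With the 6 features and all mitochondrially encoded genes left out, and TMM factors kept, the split moved less. The share of higher genes was then 53.2% in acute, 65.5% in remission and 66.1% in chronic mice against control. Against acute mice it was 49.5% in remission and 49.3% in chronic mice. No gene called both in the reported results and in an alternative changed direction between them.

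Of 186 list tests, 111 passed with the preset correlation, 15 with the correlation estimated per list and 105 with fry. Over the lists 1226 members were called in the 6 comparisons, with 1003 under the strict filter and 1395 without a filter as the extremes. Of 606 calls of genes and comparisons followed by name, 572 stayed with library totals alone, 597 with DESeq2, 570 with limma-voom and 549 with only the 6 libraries compared. The lowest number, 472, stayed with the strict filter, under which fewer genes are tested. Leaving out each library in turn kept 557, without control replicate 2, to 589, without chronic replicate 1.

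No paired analysis was possible because the replicate numbers follow the order of the records and mark no shared animal, litter or day.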

Other observations

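The tests of explanations, the splits of the libraries and the counts of genes shared by the late phases in this part were chosen only after the results had been seen, whereas the gene lists and the markers of other cells had been fixed beforehand.

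At the acute phase homeostatic genes fell while monocyte genes rose. A lower share of microglia by 1 common factor, as from added cells that make none of these genes, is argued against as the whole cause. The log2 fold changes of the 24 homeostatic genes spread 42.9 times per degree of freedom beyond their errors (chi-square p 6.19e-194), from -8.04 ± 0.38 for Fcrls to -0.99 ± 0.15 for Mertk. Dilution by cells that make some of these genes would lower them unequally, so this spread cannot test it. Recruited monocytes and macrophages may be part of the cause, since 15 of 15 tested monocyte genes rose, among them the abundant Chil3 at 369 ± 71.4 CPM, Arg1 at 155 ± 3.42 CPM and Ccr2 at 127 ± 33.4 CPM. The gate was meant to remove such cells, being CD11b positive, CD45 intermediate and Ly-6C negative, yet Ly6c2 stood at 64.6 ± 19 CPM. How much of the fall took place within microglia stays open, and a change of state by disease phase was not tested apart from the mixture, and neither were the other changes of the acute phase, among them those of immune, metabolic, TGF-beta and cell cycle genes.

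Against control mice 11 of 24 homeostatic genes were lower in remission and 11 in chronic mice, and 21 and 22 of 24 damage-associated genes were higher. The homeostatic list did not pass with the estimated correlation (adjusted p 0.198 and 0.244). Fcrls, at 102 and 135% of control, and Crybb1 (log2 fold changes 0.656 ± 0.401 and 0.578 ± 0.403 SE) did not fall. Recruited cells like those of the acute libraries are argued against, because monocyte genes stood at a median of 1.07% of their acute level in remission and 1.23% in chronic mice, with 0 of 15 above 50% in each. Dilution by cells that make as little of the homeostatic genes as the acute libraries hold is argued against as the whole cause, because 14 such genes spread 8.67 times per degree of freedom beyond their errors in remission (p 5.65e-18, from Slc2a5 to Crybb1) and 8.12 times in chronic mice (p 1.40e-16). Much of this spread came from Fcrls, Crybb1 and Slc2a5. Without them the other 11 genes spread 1.28 times in remission (p 0.235) and 3.88 times in chronic mice (p 2.74e-05), but these 3 were left out because they stood apart, which lowers the spread by itself. Dilution as part of the cause stays open. One by cells that make some of these genes was not tested, nor was a lasting damage-associated state of microglia tested apart from it.

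Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05. In each only the real split gave as many genes. The real number was 5487 for acute against control, 1168 for remission against control, 1848 for chronic against control, 4634 for remission against acute and 3610 for chronic against acute, with 0 as the highest other split in each. For chronic against remission the real number was 151 and the highest other 2. Of 100 splits for any difference among the 4 groups, the real one gave 5517 genes and no other over 500. This argues against chance, but mixing groups lowers calls.

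A set of genes separated the late phases from both control and acute mice. Higher in remission and in chronic mice than in each of the other groups were 93 genes, of which 20 stood on a fixed list, and lower were 19, of which 1 did. Monocyte genes summed to 1870 to 2850 CPM in the acute libraries, so levels there may reflect the mixture of cells sorted. A course within microglia was not tested apart from that mixture. The genes named next were chosen after their values were seen. Apoe stood at 71.6 CPM in control, 1280 in acute, 4640 in remission and 4130 in chronic mice, and Igf1 at 0.0474, 0.657, 9.79 and 18.7 CPM. The checkpoint genes Lag3 (28.7, 19.8, 215 and 115 CPM in the same order) and Pdcd1 (1.42, 5.35, 15.5 and 25.7 CPM) and the laminin Lama3 (0.52, 0.472, 11.8 and 22.1 CPM) followed this course. Of the lower genes, the cyclin Ccnd2 stood at 33.8, 48.6, 7.07 and 8.25 CPM and the interleukin receptor Il7r at 28.5, 15.8, 5.76 and 6.01 CPM.

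Mitochondrially encoded genes were higher in disease. All 15 tested rose in acute (median log2 fold change 2.07) and in chronic mice (1.31), and 13 of 15 rose in remission (1.15). With library totals alone 15 rose in each of these comparisons. Against acute mice 9 fell in remission and 6 in chronic mice. Neither cell damage nor metabolism was tested as a source.

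Several libraries stood apart in markers. In remission replicate 3 Xist stood at 2000 CPM, against at most 4.25 CPM in the other libraries, and it was the only sex-linked gene of 5 with a count there, so this library carries the marker of a female and the other 11 those of males. The same library held 1830 CPM of immediate-early genes against 266 to 788 CPM elsewhere, so sex and handling cannot be separated from its other differences. Remission replicate 1 held 746 CPM of myelin genes, 62.2 CPM of neutrophil genes and 55 CPM of neuronal genes, with Mbp at 343 CPM and S100a9 at 9.41 CPM. RNA of other cells or debris in the sorted fraction is a candidate source there, although the gate on CD11b, CD45 and Ly-6C was meant to exclude oligodendrocytes and neurons. Leaving out remission replicates 1 and 3 leaves 1 remission library, so counts of called genes cannot show how far these replicates set the results.

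B and plasma cell genes had too few members past the filter for a list test, and their summed level was 53.3 to 78.7 CPM in control, 22.2 to 38.9 in acute, 45 to 60.4 in remission and 37.7 to 58.2 CPM in chronic libraries. Flt1 rose in each disease phase against control mice, to 9.87 ± 0.796, 12.8 ± 5.37 and 38.6 ± 18.1 CPM, while Pecam1, another gene of endothelial cells, stood at 0.536 ± 0.33 CPM in chronic and 3.36 ± 0.527 CPM in control mice. Endothelial cells, which the gate on CD11b and CD45 was meant to exclude, were not tested as the source of Flt1.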
